A study of Mus musculus with 6 samples.

How the data were processed

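Poly-A RNA was sequenced from mouse leukemia cells made with MLL-AF9, a fusion oncogene of human acute myeloid leukemia. Per the labels, sorted stem and progenitor cells (lineage negative, Sca-1 positive, c-Kit positive) of Alox5-/- or wild-type (WT) C57BL/6J donors had been transduced with an MLL-AF9 retrovirus, and samples were sorted by flow cytometry into a lysis reagent before cDNA was made with the SMARTer amplification kit. Each group held 3 libraries, all untreated. The labels call them biological replicates and do not say which animals they came from, so p-values measure only the spread between these samples.

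The authors deposited a table of raw read counts per gene. Counting was done with HTSeq on the mouse build mm10, per the submitters' processing notes, which also name DESeq2. The aligner, the tool versions, the annotation release and the strand setting are not given in the sources used here. The deposited count table held 46983 genes, of which 25300 were at 0 in all 6 libraries, and 27 gene symbols had been turned into calendar dates and were restored through their gene identifiers. A further 5 summary rows name no gene and were left out of library sizes and tests. They held reads aligned to more than one place (24.4 to 24.8% of all reads), reads outside annotated genes (9.10 to 10.2%), ambiguous reads (0.523 to 0.547%), reads not aligned (4.57 to 5.78%) and reads of low mapping quality (0%). Reads from near-identical gene copies therefore went largely uncounted, and values of multigene families such as Stfa1, Gstm1 and Gstm5 are uncertain. Because the strand setting is not given, overlapping and antisense genes, such as Xist and Tsix, cannot be told apart with certainty. Gene positions came from the GENCODE vM21 annotation of the same build, in which 98.95% of the gene identifiers were found. The release used by the authors may differ in gene models.

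From the counts, differential expression was computed in R 4.3.3 with edgeR 4.0.16, using TMM scaling, the default expression filter and the quasi-likelihood F-test of Alox5-/- against WT with no covariate. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Standard errors (SE) of log2 fold changes were derived from the coefficient and its F statistic. Normalised expression is given as CPM (read counts scaled to a common library size, with TMM factors), as mean ± SD of 3 libraries. Before the data were examined, 22 gene lists were fixed. They covered the leukotriene pathway, the MLL fusion program, stem cell, myeloid, lymphoid, erythroid, megakaryocyte, macrophage and stromal markers, cell cycle, p53, apoptosis, Wnt, interferon, NF-kB, immediate early, drug metabolism, oxidative stress, adhesion, glycolysis, mitochondrial and sex-linked genes. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 19 lists. Camera with an estimated correlation and fry were run beside it. Camera compares the genes of a list with the other genes, while fry asks only whether a list's genes move on balance one way. Called genes within 5 Mb of Alox5 were compared with other tested genes by a two-sided Fisher's exact test, leaving out Alox5 itself and tested genes without a position in the annotation.

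The genes named were also fixed by a rule beforehand. They were Alox5, Alox5ap, Lta4h, Ltb4r1 and Ltb4r2; the 12 largest rises and 12 largest falls among called genes with a mean of at least 5 CPM and no overlap between the groups' libraries; up to 4 called members of each list by smallest p; and up to 5 called neighbours of Alox5. One gene that this rule names is not reported here. Genes named outside this rule are said to have been chosen after their values were seen.

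Gene counts per library were 30677796, 28985597 and 29181266 in Alox5-/- and 30305344, 30239105 and 38695948 in WT, or 60.0 to 60.9% of all reads. A count of 0 allows up to 3 counts, which is 0.0786 to 0.103 CPM. These floors cover counting error only, since amplified reads without molecular identifiers are not independent molecules. No pair of libraries agreed within sampling noise: chi-square per degree of freedom was 2.20 to 10.4 within groups, highest for the pairs with Alox5-/- replicate 2 (9.19 and 10.4), and 35.8 to 51.0 between groups. Simulated counts were drawn from gene means over the 6 libraries and the size of each library, and 13569 genes passed the filter. In them 50 genes were changed at each fold given below, while 53.84% of tested genes were called in the data. The test was tried on these simulated counts, and its rates need not hold for the real comparison. It recovered 58% of genes changed 1.2-fold, 72% of those changed 1.5-fold, 92% of those changed 2-fold and 98% of those changed 4-fold, with 11 false calls among 13345 unchanged genes.

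Alternatives fixed beforehand were the DESeq2 1.42.0 Wald test, limma-voom, size factors of DESeq2 and upper-quartile scaling in edgeR, no filter, a filter of 5 CPM in 3 libraries, a robust fit, the replicate number as a block, a 2-fold minimum, a 10 Mb window, and each replicate left out in turn.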

Results

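RNA was profiled in MLL-AF9 leukemia cells of 2 genotypes, with 3 libraries from Alox5-/- and 3 from WT cells. Alox5 encodes 5-lipoxygenase, the enzyme that starts leukotriene synthesis from arachidonic acid. The series asks how Alox5 and signalling by leukotriene B4 through its receptor bear on the survival of leukemic stem cells and on resistance to chemotherapy. All 6 libraries were untreated, with 28985597 to 38695948 gene counts each.

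Alox5 transcript was lower in Alox5-/- cells and was still detected in all 3 libraries. It stood at 64.2 ± 1.87 CPM in Alox5-/- and 105 ± 1.87 CPM in WT (SD, n = 3 each), 1.63-fold lower, with a log2 fold change of -0.70 (SE 0.04; edgeR adjusted p = 7.65e-10). Raw counts were 2044, 1815 and 1929 in Alox5-/- and 3059, 3137 and 4035 in WT, so that every Alox5-/- library lay below every WT library after scaling. Alox5 (ENSMUSG00000025701) lies on the minus strand of chromosome 6 from 116410077 to 116461178 (mm10), and the annotation gives 14 exons for its transcript Alox5-201. The counts cover the whole gene, and the part altered in the Alox5-/- allele is not given in the sources used here. The count is therefore only a partial check of the genotype labels.

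The other genes needed to make and sense leukotriene B4 differed from one another. Lta4h, the hydrolase that forms leukotriene B4, was 412 ± 7.5 CPM in Alox5-/- and 584 ± 6.81 CPM in WT, a log2 fold change of -0.51 (SE 0.03; edgeR adjusted p = 2.87e-09). Alox5ap, which presents arachidonic acid to 5-lipoxygenase, was 164 ± 5.46 against 199 ± 5.03 CPM, a log2 fold change of -0.27 (SE 0.03; edgeR adjusted p = 1.07e-05). Ltb4r1, the high-affinity leukotriene B4 receptor, was 18.4 ± 0.711 CPM in Alox5-/- and 17.9 ± 1.21 CPM in WT, a difference within the spread of the libraries (log2 fold change 0.04, SE 0.06; edgeR adjusted p = 0.614). Ltb4r2, the low-affinity receptor, had 49 counts over all 6 libraries and did not pass the expression filter. In the whole leukotriene and eicosanoid list, 9 of 20 tested members rose, 4 fell and 7 were not called. Pla2g4a, the phospholipase that releases arachidonic acid, rose by 0.44 on the log2 scale, and Ptger2, a prostaglandin E2 receptor, rose from 0.229 ± 0.092 to 1.65 ± 0.142 CPM, while Tbxas1, thromboxane synthase, fell by 0.65. The list as a whole was not called by camera (adjusted p = 0.787).

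**Figure D1:**
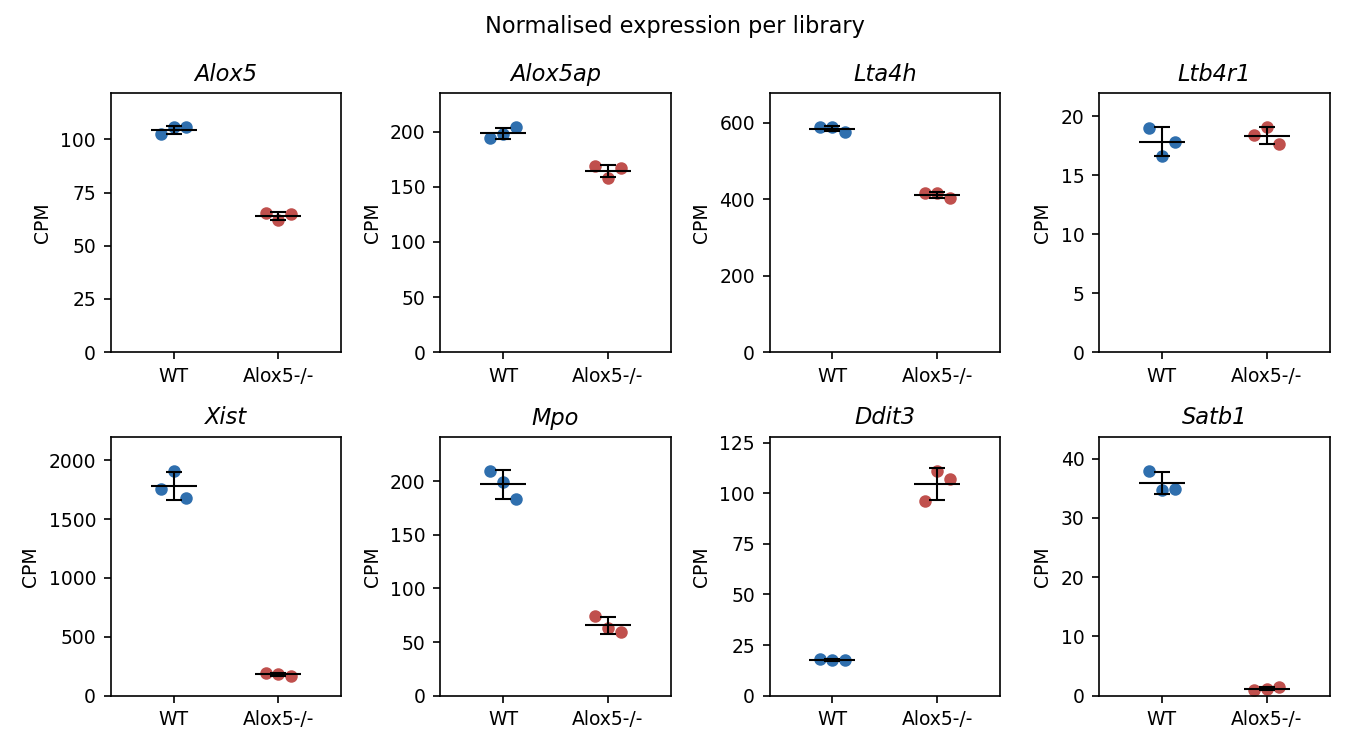
Normalised expression in CPM (y axis, from 0) of 8 genes in the 3 WT and 3 Alox5-/- libraries; points are libraries, horizontal lines means and bars SD. Alox5 is at 105 CPM in WT and 64.2 CPM in Alox5-/-, while the Ltb4r1 libraries of the groups overlap.

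Across the transcriptome, Alox5-/- and WT cells differed widely, mostly by small amounts. Among called genes with a mean of at least 5 CPM, the highest rises in Alox5-/- cells were in Ppic, a peptidyl-prolyl isomerase (23.9-fold), Snx7, a sorting nexin (9.42-fold), F7, coagulation factor VII (7.66-fold), Cldn11, a tight junction protein (6.15-fold), and Ddit3, the stress transcription factor CHOP (5.93-fold). The deepest falls were in Satb1, a chromatin organiser of progenitors and T cells (30.4-fold), Zcchc3, a zinc finger protein (21.1-fold), Ptpn3, a tyrosine phosphatase (15.7-fold), Tcf24, a basic helix-loop-helix factor (13.4-fold), and the transcript D330045A20Rik. Of 13705 tested genes, 7379 (53.84%) were called, 3673 higher and 3706 lower. A change under 1.5-fold was found in 5798 of them (78.57%), and 374 higher and 252 lower genes differed at least 2-fold.

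Ppic, at 53406332 to 53418115 on chromosome 18, was 30.7 ± 0.971 CPM in Alox5-/- and 1.27 ± 0.054 CPM in WT, a log2 fold change of 4.58 (SE 0.09; edgeR adjusted p = 2.21e-14). Snx7 (3.24) and F7 (2.94) lay on chromosomes 3 and 8, and Cldn11 had a log2 fold change of 2.62. Ddit3, at 127290774 to 127296288 on chromosome 10, was 105 ± 7.83 against 17.6 ± 0.384 CPM (log2 fold change 2.57, SE 0.06; edgeR adjusted p = 1.09e-13). The other large rises were Frzb, a secreted Wnt antagonist (2.28), Ttc25, a ciliary protein (2.26), Thy1, a surface glycoprotein (2.15), Nrp1, a co-receptor for semaphorins and VEGF (2.14), Mamdc2 (2.11), Soat2, a cholesterol acyltransferase (2.07), and the adhesion molecule Vcam1 (2.04), all as log2 fold changes.

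Satb1, at 51736187 to 51833290 on chromosome 17, fell from 35.9 ± 1.79 CPM in WT to 1.18 ± 0.294 CPM in Alox5-/-, a log2 fold change of -4.92 (SE 0.11; edgeR adjusted p = 1.09e-13). Zcchc3 (-4.40), Ptpn3 (-3.97), Tcf24 (-3.74) and D330045A20Rik (-3.58) followed. Stc2, a secreted glycoprotein, was 5.74 ± 0.606 CPM in Alox5-/- and 60.0 ± 8.64 CPM in WT (log2 fold change -3.38, SE 0.11; edgeR adjusted p = 3.69e-12). Xist, the RNA that coats and silences the inactive X chromosome, was 181 ± 14.3 against 1782 ± 117 CPM (log2 fold change -3.30, SE 0.06; edgeR adjusted p = 1.38e-14). It lies at 103460366 to 103483254 on chromosome X. The remaining large falls were Clec11a, a hematopoietic growth factor (-3.12), Stfa1, a cystatin with near-identical copies whose value is uncertain (-2.45), Col19a1, a collagen (-2.44), Cpa3, the mast cell carboxypeptidase (-2.21), and Phlda3, a p53 target (-2.05). The libraries of the groups did not overlap for 8218 of the 13705 tested genes (59.96%), against 10% by chance; these large rises and falls were picked among such genes.

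**Figure D2:**
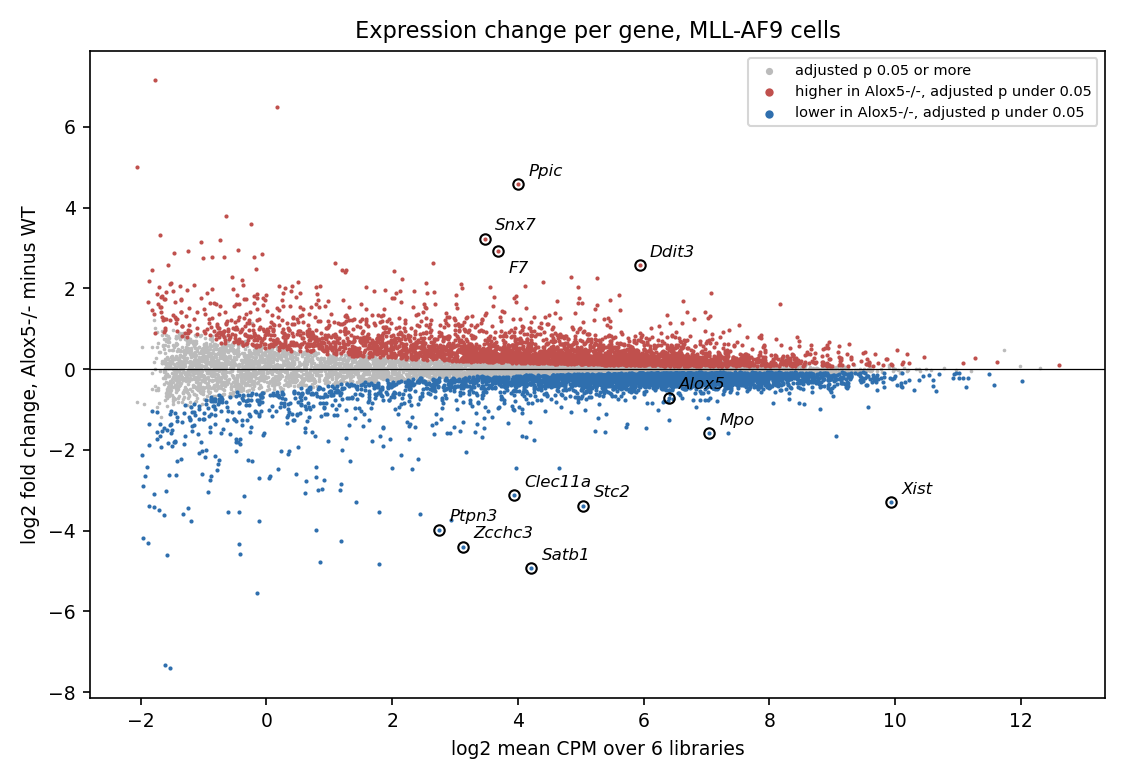
Log2 fold change of Alox5-/- minus WT (y axis) against log2 mean CPM over 6 libraries (x axis) for 13705 tested genes; red and blue points are the 3673 higher and 3706 lower genes at an edgeR adjusted p under 0.05, grey points the rest. Circles mark named genes, from Ppic at 4.58 to Satb1 at -4.92.

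The spread within genotypes was small, with a biological coefficient of variation of 3.70%. The share of reads outside annotated genes was 9.76 ± 0.39% in Alox5-/- and 9.24 ± 0.13% in WT (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 allows).

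Proliferation genes fell together by small amounts. In the cell cycle list, 26 of 30 tested members fell, none rose and 4 were not called, with a median log2 fold change of -0.22. The DNA helicase subunits Mcm4 and Mcm5 fell by 0.48 and 0.34 on the log2 scale, cyclin E1 (Ccne1) by 0.66 and the mitotic kinase Plk1 by 0.42. The list was lower by camera (adjusted p = 3.53e-07), but adjusted p = 0.25 with an estimated correlation.

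Of 24 tested p53 targets, 13 fell, 6 rose and 5 were not called, with a median log2 fold change of -0.27 (camera adjusted p = 0.0284; adjusted p = 0.703 with an estimated correlation). Phlda3 and Zmat3, an RNA-binding protein, fell by 2.05 and 1.07. Gadd45a, a stress gene, and Sesn2, a sestrin induced by amino acid lack as well as by p53, rose by 1.68 and 0.60, with Gadd45a highest in Alox5-/- replicate 2 (132, 172 and 148 CPM in replicates 1 to 3). The call was lost without Alox5-/- replicate 1 (adjusted p = 0.0926) and with the stricter filter (adjusted p = 0.107).

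Genes of granulocyte and monocyte maturation were lower on balance. Mpo, the myeloperoxidase of granulocyte precursors, was 65.6 ± 7.76 CPM in Alox5-/- and 197 ± 13.4 CPM in WT, a log2 fold change of -1.59, and S100a8, a calcium-binding protein of neutrophils, was 3.15-fold lower. Cybb, the catalytic subunit of the phagocyte oxidase, fell by 1.46 on the log2 scale, and Lcn2, a neutrophil granule protein, rose by 1.03. Of 25 tested members 14 fell, 6 rose and 5 were not called (median -0.13; camera adjusted p = 0.017; adjusted p = 0.25 with an estimated correlation).

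Several inflammatory and stimulus-responsive groups were higher. In the NF-kB list, 10 of 18 tested members rose and 2 fell (median 0.18; camera adjusted p = 0.000298; adjusted p = 0.25 with an estimated correlation). The chemokines Ccl4 and Ccl3 were 67.6 ± 2.03 against 20.5 ± 0.703 CPM and 249 ± 9.63 against 116 ± 3.95 CPM, and Tnfaip2 and Nfkbiz, both induced by NF-kB signalling, rose by 0.68 and 0.88 on the log2 scale. Of 22 immediate early genes, 14 rose and 5 fell (median 0.42; camera adjusted p = 0.0186; adjusted p = 0.797 with an estimated correlation). Egr1, an early growth response factor, went from 0.735 ± 0.057 to 4.08 ± 1.48 CPM, and Klf6, Btg1 and Jun rose by 0.74, 0.70 and 0.93. Alox5-/- replicate 2, the library farthest from the others of its group, had the highest Egr1 (2.76, 5.68 and 3.80 CPM in replicates 1 to 3) and Jun (17.0, 22.2 and 17.8 CPM). Without it both genes were still called, with log2 fold changes of 2.15 and 0.81, and the list had an adjusted p of 0.0266. This list was not called with the stricter filter (adjusted p = 0.07).

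Interferon response genes rose in 14 of 23 tested cases and fell in 1 (median 0.43; camera adjusted p = 0.0408; adjusted p = 0.473 with an estimated correlation). Oas3, an antiviral oligoadenylate synthetase, rose by 0.83, Irf7 by 0.78 and Ifit2 by 0.53 on the log2 scale, and Usp18, a protease that removes ISG15, rose 2.29-fold. The call was lost with the stricter filter (adjusted p = 0.51), with upper-quartile scaling (0.051), and without Alox5-/- replicate 1 (0.0763) or WT replicate 3 (0.0562). Macrophage and dendritic cell markers rose in 9 of 15 tested cases and fell in 4 (median 0.25; camera adjusted p = 0.0284; adjusted p = 0.25 with an estimated correlation). Vcam1 (2.04), Itgax, an integrin of dendritic cells (1.06), and Cd68 (0.47) rose, and Slc40a1, the iron exporter, fell by 0.67. Adgre1, the macrophage marker F4/80, chosen after its values were seen, was lower (32.9 ± 1.4 CPM in Alox5-/- and 43.1 ± 1.93 CPM in WT; edgeR adjusted p = 1.23e-05). C1qa, another macrophage gene chosen in the same way, had 1 count in 6 libraries, and the call was lost with no filter on low counts (adjusted p = 0.053).

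Glycolysis genes rose in 9 of 20 tested cases and fell in 1 (median 0.11; camera adjusted p = 0.0408; adjusted p = 0.863 with an estimated correlation). Aldoc, an aldolase, was 43.4 ± 1.44 CPM in Alox5-/- and 16.5 ± 1.5 CPM in WT, Pdk1, a pyruvate dehydrogenase kinase, rose by 0.60, and the phosphofructokinases Pfkm and Pfkp rose by 0.42 and 0.32. The call was lost with the stricter filter (adjusted p = 0.07), the robust fit (0.0654), and without Alox5-/- replicate 1 (0.0926), WT replicate 2 (0.0639) or WT replicate 3 (0.0708).

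**Figure D3:**
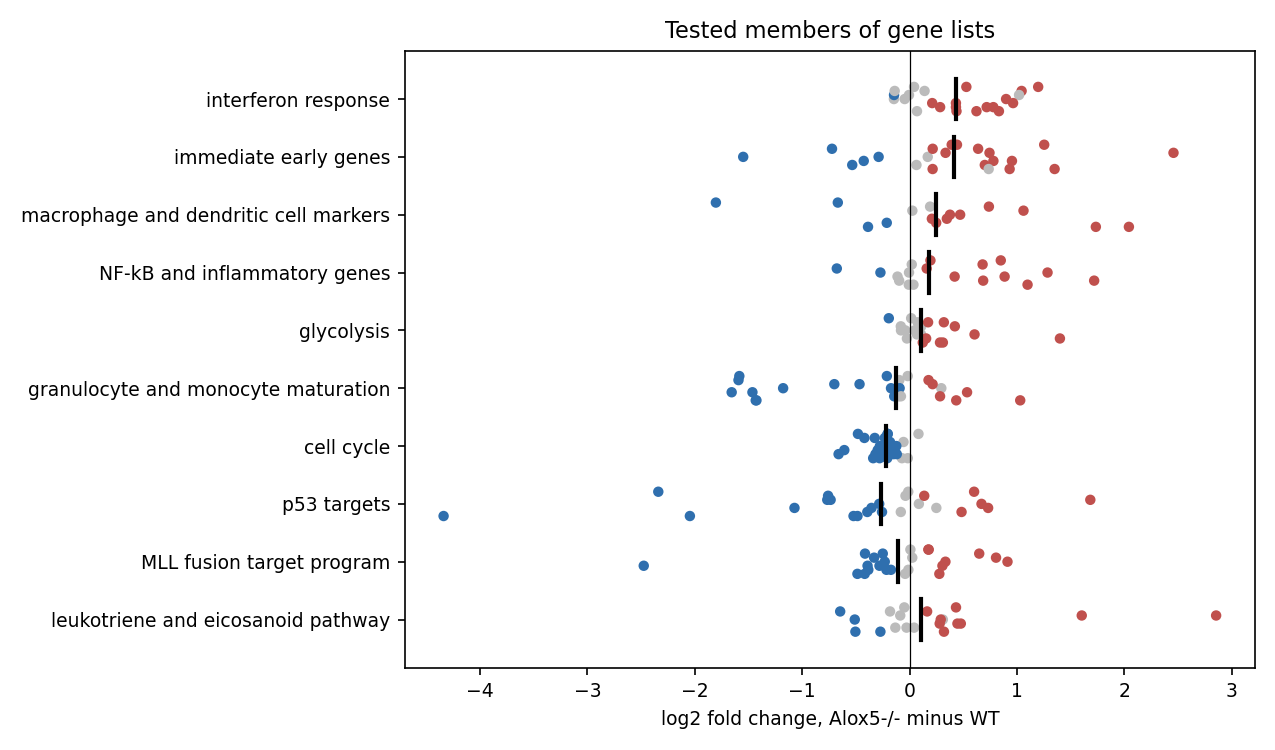
Log2 fold change of Alox5-/- minus WT (x axis) of the tested members of 10 gene lists; red and blue points are members called higher and lower by edgeR, grey points the rest, and black bars list medians. Medians run from -0.27 for p53 targets to 0.43 for interferon response genes.

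Among the lists that camera did not call, the MLL fusion program moved both ways, with 8 of 24 tested members higher and 12 lower (camera adjusted p = 0.311). Eya1, a transcriptional co-activator, was 1.51 ± 0.251 CPM in Alox5-/- and 8.42 ± 0.243 CPM in WT, Hoxa11 and Hoxa10 fell by 0.42 and 0.33 on the log2 scale, and the receptor kinase Flt3 rose by 0.91. Of the stem cell markers only 8 passed the filter, 2 of them higher (Cd34 0.36, Erg 0.24) and 2 lower (Kit -0.23, Cdkn1c -0.71; camera adjusted p = 0.98). Ly6a, which encodes Sca-1 and was chosen after its values were seen, was at 0.763 ± 0.158 CPM in Alox5-/- and 1.06 ± 0.169 CPM in WT. Megakaryocyte, mast cell and basophil markers had 3 higher and 3 lower of 9 (camera adjusted p = 0.391). The mast cell and basophil genes Cpa3 (-2.21) and Hdc, histidine decarboxylase (-1.45), fell, and the platelet integrin Itgb3 (0.87) and Cd9 (0.75) rose.

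Drug transport and nucleoside metabolism genes numbered 10 higher and 8 lower of 26 (camera adjusted p = 0.98), with Gstm5 (0.62) and Mgst1 (0.61) higher and Rrm1 (-0.37) and Gstm1 (-0.34) lower. Oxidative stress genes numbered 8 higher and 12 lower of 24 (camera adjusted p = 0.98). Slc7a11, the cystine transporter, was 93.1 ± 4.63 against 45.9 ± 3.31 CPM, Gpx3 (0.83) and the ferritin gene Fth1 (0.41) were higher, and G6pdx (-0.44) was lower. Adhesion receptors had 6 higher and 5 lower of 20 (camera adjusted p = 0.98); the chemokine receptor Ccr1 fell by 0.44 on the log2 scale, and Cd93 and Cd47 rose by 0.48 and 0.38. Apoptosis regulators had 8 higher and 7 lower of 26 (camera adjusted p = 0.98), with Bcl2 higher (0.28) and Bax (-0.39), Bak1 (-0.22) and Apaf1 (-0.22) lower. Wnt targets had 5 higher and 3 lower of 14 (camera adjusted p = 0.98), among them Rnf43 (-0.98), Jun (0.93), Myc (0.27) and Cd44 (-0.22).

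Of 13 mitochondrially encoded genes only 7 passed the filter, 4 of them lower and 3 not called (camera adjusted p = 0.462). Why the rest fell short was not tested. Lower were mt-Cytb (-0.22), mt-Nd1 (-0.21), mt-Nd2 (-0.20) and mt-Nd4 (-0.11). The mt-Nd4 call was lost with upper-quartile scaling (edgeR adjusted p = 0.0885). B, T and NK cell markers had 2 higher (Lck 0.33, Nkg7 0.58) and 2 lower (Bcl11b -0.84, Vpreb1 -1.52) of 6 (camera adjusted p = 0.98). Cd3e, also chosen after its values were seen, had no count in any library, which allows up to 0.103 CPM. Erythroid and stromal lists had 3 tested members each and were not tested as lists. Among erythroid genes the transferrin receptor Tfrc was 302 ± 14 against 594 ± 30.9 CPM and Car2 rose by 0.89. Pecam1 (0.18) and Pdgfrb (0.22) were higher among stromal and endothelial genes, the Pdgfrb libraries of the groups overlapping and its call lost with DESeq2 (adjusted p = 0.0981). Of the sex-linked list, Xist alone passed the filter.

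Over all genes and adjusted over the list alone, the counts of called members were equal, except for a further lower member among megakaryocyte, mast cell and basophil markers (4) and among apoptosis regulators (8). Median, mean and camera direction differed in sign for 6 uncalled lists: stem cell markers (median 0.02, mean -0.09, camera higher), B, T and NK cell markers (0.18, -0.18, higher), megakaryocyte, mast cell and basophil markers (0.02, -0.32, lower), apoptosis (-0.01, 0.01, lower), oxidative stress (-0.07, 0.01, higher) and adhesion (0.02, -0.02, lower). At the preset correlation 8 of 19 lists were called, 5 higher and 3 lower. With an estimated correlation 0 were, 3 having an unadjusted p under 0.05, and fry called 13.

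Genes near Alox5 did not differ detectably from genes elsewhere in how often they were called. Within 5 Mb, 53 of 89 tested genes (59.55%) were called, against 7312 of 13574 other genes (53.87%), an odds ratio of 1.26 (95% interval 0.809 to 1.99; two-sided Fisher's exact p = 0.289). The called neighbours with the smallest p were Camk1, a calmodulin-dependent kinase (0.72), Irak2, a kinase of interleukin-1 signalling (0.73), the zinc finger gene Zfp239 (1.03), Ghrl, the ghrelin gene, and Arpc4, an actin nucleation subunit (-0.33), with log2 fold changes in parentheses. Ghrl was 1.42 ± 0.124 CPM in WT and 0.056 ± 0.021 CPM in Alox5-/-, where it lay under the level that a count of 0 allows.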

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

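The share of reads outside annotated genes, a summary value that no comparison of genes used, was singled out after its values per library had been seen. It was 9.76 ± 0.39% in Alox5-/- and 9.24 ± 0.13% in WT (SD, n = 3 each), above the level in the control libraries. The difference had a two-sided exact permutation p of 0.1, the smallest that 3 against 3 allows. No group had enough libraries to test for an outlying library.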

How the results depend on the processing

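The count of called genes stayed within 1.5 times of 7379 under every alternative of tool, scaling, filter, robust fit and replicate left out: 6259 with DESeq2, 7374 with limma-voom, 6219 with the stricter filter, 7622 with no filter, and 6583 to 7251 with a replicate left out. A 2-fold minimum left 626, with 374 higher and 252 lower. Alox5 was lower under DESeq2, both scalings, both filters, the robust fit and the block, and with each replicate left out (-0.72 to -0.67 with a replicate left out). Upper-quartile scaling gave 4076 higher and 3201 lower genes (56.01% higher, against 49.78%). Scaling moved the median of all genes by at most 0.03. For 107 named genes, 1371 of 1382 refits kept direction and side of the threshold, and 10 lost the call (Pdgfrb and mt-Nd4). In 1 refit the sign changed, Ltb4r1 without WT replicate 2 (-0.0047 to 0.088 over the replicates left out). Most of these genes had been picked by size of change or smallest p in the same libraries. Their stability therefore says little about that of other called genes. The odds ratio near Alox5 was 1.02 to 1.49 with a replicate left out and 1.40 within 10 Mb (Fisher's exact p = 0.0515).

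The replicate numbers did not pair the samples. After the mean log2 CPM of each genotype was subtracted per gene, same-numbered libraries had correlations of -0.0235, -0.0771 and 0.0217. Only WT replicate 3 correlated best with the library of its own number in the other genotype. With the replicate number as a block, 7029 genes and 8 lists were called and Alox5 was at -0.70.

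The gene lists depended most on the test. The stricter filter called 4 lists, an estimated correlation 0, and leaving out a replicate 5 to 8. Fry, which does not compare a list with other genes as camera does, called 13. With an estimated correlation, adjusted p was 0.25 for granulocyte and monocyte maturation, macrophage and dendritic cell markers, cell cycle and NF-kB genes, 0.703 for p53 targets, 0.473 for interferon, 0.797 for immediate early genes and 0.863 for glycolysis. With the stricter filter it was 0.107 for p53 targets, 0.51 for interferon, and 0.07 for immediate early genes and glycolysis, with fewer genes tested. Interferon had 0.051 with upper-quartile scaling, macrophage and dendritic cell markers 0.053 with no filter, and glycolysis 0.0654 with the robust fit; the cause was not tested. With a replicate left out, adjusted p ran from 0.00552 to 0.0144 for granulocyte and monocyte maturation, 0.022 to 0.0396 for macrophage and dendritic cell markers, 1.72e-07 to 1.46e-06 for cell cycle, 0.0043 to 0.0926 for p53 targets, 0.0355 to 0.0763 for interferon, 0.000176 to 0.000603 for NF-kB, 0.00201 to 0.0305 for immediate early genes, and 0.00234 to 0.0926 for glycolysis.

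Uncalled lists changed sign at these adjusted p, the cause not tested: leukotriene, apoptosis and drug metabolism with the stricter filter (0.999 each); stem cell markers with no filter (0.965) and without Alox5-/- replicate 3 (0.957; 0.854 to 0.999 over the replicates left out); B, T and NK cell markers with upper-quartile scaling (0.998), no filter (0.965), the robust fit (0.992) and without Alox5-/- replicates 1 or 3 or WT replicate 2 (0.854 to 0.999 over the replicates left out); Wnt targets without WT replicate 3 (0.949; 0.854 to 0.999); and oxidative stress with the replicate block (0.967) and without Alox5-/- replicate 2 or WT replicates 1 or 2 (0.949 to 0.999). Depth limits genes near 0.1 CPM.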

Other observations

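The tests of chromosome segments, calls on other chromosomes, shared leukemia, X-linked and Y-linked genes, and the ATF4 and chaperone lists were chosen after their results or some members had been seen. The Fisher test of genes near Alox5 was fixed before the data were examined, and the bounds for reading it as flanking DNA were set after its shares had been seen. The second p53 list was written after the first had been seen but before its own members were, and the tests of GC content and long transcripts were set before their results. Genes named here were chosen after their values were seen.

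Genes of the amino acid response, driven by the transcription factor ATF4, rose broadly in Alox5-/- cells. Of 30 genes listed after Ddit3, Trib3 and Nupr1 had drawn attention, 27 rose and 2 fell (median log2 fold change 0.56). Trib3, a pseudokinase, was 212 ± 22.8 against 57.8 ± 4.0 CPM and highest in Alox5-/- replicate 2 (191, 236 and 210 CPM in replicates 1 to 3), Nupr1 76.4 ± 3.70 against 21.3 ± 0.681 CPM, and Cth, the enzyme that makes cysteine from cystathionine, 135 ± 5.32 against 60.6 ± 4.06 CPM. Asns, asparagine synthetase, rose by 0.61, Pck2 by 0.81 and the aminoacyl-tRNA synthetases Sars and Wars by 0.60 and 0.57 on the log2 scale, while Stc2, on the same list, fell by 3.38. Among the 15 members not looked at when the list was written, 14 rose and 1 fell. Camera gave them an unadjusted p of 1.63e-17, or 0.0198 with an estimated correlation. This goes with a broad rise rather than a change of the genes first seen. By camera with an estimated correlation, the fixed cell cycle, NF-kB and macrophage lists had an unadjusted p of 0.0335, 0.0392 and 0.048. Each was 0.25 after adjustment, so the added lists did not pass a test that these failed.

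Heat shock and endoplasmic reticulum chaperones fell as a group. Hspa8, the constitutive cytosolic HSP70, was 260 ± 11.2 CPM in Alox5-/- and 811 ± 28.0 CPM in WT, Hsph1 77.5 ± 1.11 against 150 ± 3.13 CPM, and the lumenal chaperone Hspa5 fell by 0.50 on the log2 scale. All 22 tested members fell (median -0.42), among them 15 that had not been looked at when the list was written. For these 15, camera gave an unadjusted p of 1.89e-10, or 0.0145 with an estimated correlation. Ddit3 and Hspa5, both induced in the unfolded protein response, thus moved in opposite directions. Hspa8 has processed copies in the genome, and its count is uncertain to that extent.

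The number of called genes, 7379, was weighed first. The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05 (1 split reached the real value in each test). Each of the other 9 held both genotypes in both groups, so that the difference between genotypes widened the spread within groups. Their low counts of edgeR calls therefore cannot show whether the real split stands out. They gave 0 edgeR calls (62 to 369 genes at an unadjusted p under 0.05), which leaves their Fisher p near Alox5 at 1 against 0.289. Camera at the preset correlation still called 1 to 5 lists in them against 8 in the real split. A trend with GC content and transcript length took up little of the variance (R squared 0.00565). No chromosome or long segment moved as a whole, the farthest median of 25 neighbouring genes being 0.246 from 0. These values argue against both as the main cause. Of 12987 tested genes not placed on the chromosome of Alox5, which include genes without a position, 6983 (53.8%) were called. Those placed on other chromosomes lie outside any DNA flanking Alox5. Whether such DNA acted on distant genes was not tested. It stays open whether the Alox5-/- libraries differ from WT by genotype or because each set of 3 came from a single leukemia. Handling or sequencing shared only by the libraries of a genotype could not be told apart from genotype either, and was not tested. The labels name no animals. The coefficient of variation of 3.70% cannot decide, since the spread among separate leukemias, or within a single leukemia, was not measured. For the 53 called genes within 5 Mb of Alox5, a part of flanking DNA also stays open (odds ratio 1.26).

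Low Xist in Alox5-/- cells, 9.83-fold under WT, was weighed next. Male cells with a Y chromosome are argued against by a mean of 0 counts of 4 Y-linked genes in Alox5-/-. Male cells without a Y chromosome would not be seen by these counts. Reactivation of the inactive X is argued against by a median log2 fold change of -0.0223 over 387 other X-linked genes. Loss of long transcripts is argued against by a median of 0.00526 over 217 genes whose longest annotated transcript is at least 10 kb. These genes averaged at least 8 CPM, and the transcripts present may be shorter than the longest annotated. All 9 tested genes known to escape X inactivation were lower, with a median of -0.585, and 0 of 10000 random sets of other X-linked genes were as low. Eif2s3x fell by 0.87, Utp14a by 0.76 and Kdm5c by 0.57, so that loss of the inactive X in most Alox5-/- cells is a candidate explanation, found on these data. Whether such a loss came with a leukemic clone or with the genotype was not tested.

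Lower p53 targets in Alox5-/- cells were weighed last. After removal of the GC and length trend the median of the list was -0.349, so that the trend does not account for it. A second list of p53 targets, sharing no gene with the first, was also lower (median -0.21). Of its 19 tested members, 11 fell and 3 rose, among them Gtse1 (-0.83) and Rrm2b (0.84). Camera gave an unadjusted p of 0.00572, or 0.107 with an estimated correlation. This goes with a wider fall only at the preset correlation. Trp53 transcript itself was 128 ± 7.65 against 158 ± 11.1 CPM (log2 fold change -0.31; edgeR adjusted p = 0.000103). Mdm2, a direct p53 target, was 120 ± 4.24 against 123 ± 2.59 CPM and was not called (edgeR adjusted p = 0.378), and p53 activity itself was not measured.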
